A study of Mus musculus with 16 samples.

How the data were processed

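RNA from HL-1 cells, a mouse atrial cardiomyocyte line, was hybridised to 16 single-colour Agilent arrays, 4 for each of 4 treatments of 6 h: vehicle (PBS), 100 nM dexamethasone (Dex), 10 nM estradiol (E2) and both (Dex+E2). The series design states 4 independent experiments. Cy3-labelled cRNA was made from total RNA, per the labels' protocols, and the spots were quantified with Agilent Feature Extraction version 12, per the submitters' processing notes. Per the file headers, the processed signal of each spot is a background-subtracted intensity on a linear scale. A deposited table of the whole series held log2 values for the same 16 arrays. Its 16 columns had the same sorted values and a median of 4.698 each, and every column correlated best with its own array (lowest r = 0.999 across probes), so the log2 scale, the shared distribution and the absence of centring by gene were read from the values. The method behind it is not given in the sources used here. That table was used only as an alternative.

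Groups and array numbers were taken from the labels alone. Each array held 43379 non-control spots for 41174 probes. Control spots and spots with a non-uniformity or population outlier flag were left out, spots of one probe were averaged, and the level of a probe was log2 of the processed signal minus the 75th percentile of that array. The 75th percentile itself lay between 402 and 557 intensity units. Between 58.7% and 65.6% of probes were well above background per array, 0 were saturated, and the median coefficient of variation between replicate spots was 3.68% to 6.74%. The number of arrays limits the precision of every comparison. A probe was kept when it was well above background on all 4 arrays of at least 1 group, which left 24455 probes, and a gene was represented by its probe with the highest mean over the 16 arrays, giving 17773 genes. The files used here carry accessions and no gene symbols. Accessions without their version matched the RefSeq gene table of assembly GRCm38.p6 for 28223 probes, naming 19096 genes, and the other 12951 probes kept their accession. Of the genes tested, 13031 had a symbol and 4742 did not.

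Comparisons were fitted with limma 3.58.1 (lmFit, then eBayes with a trend) in R 4.3.3 on all 16 arrays with treatment as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, per comparison. The 6 comparisons were Dex, E2 and Dex+E2 against vehicle, Dex+E2 against Dex, Dex+E2 against E2, and the Dex by E2 interaction. The effects of Dex and of E2 averaged over the other treatment were fitted as well. The shift of 30 gene lists was tested with camera at its preset inter-gene correlation, and again with the correlation estimated from the data. The second version has no more degrees of freedom than the residuals of its fit, 12 over all 16 arrays and 2 within a slide. A list can hardly pass it within a slide, so its values there do not decide whether a list shifted. Adjustment was over all 180 list tests of a fit. Within a single slide it was over that slide's 30 list tests alone, so those values are not directly comparable with the others. Where a group was not well above background on any of its arrays, the fold is given as a bound, from the bright group's mean against the mean over the dim group's arrays of the higher of the lowest signal well above background and the probe's own signal. The arrays lay on 4 slides of 4. Vehicle 1 and 2 shared slide 1 with Dex 1 and 2, Vehicle 3 and 4 shared slide 2 with E2 1 and 2, Dex 3 and 4 shared slide 3 with Dex+E2 1 and 2, and E2 3 and 4 shared slide 4 with Dex+E2 3 and 4. Results are therefore also given with slide as a block and within each slide. Within each slide the first label named took positions 1 and 2 and the other positions 3 and 4, so within a slide position and label cannot be told apart. Fits with slide as a block draw on differences within slides, so position enters them as well, except in the interaction, where it cancels. Dex+E2 and vehicle shared no slide and are linked there through the labels Dex and E2, so position enters that comparison more than once. On slides 2 and 3 the labels also differ in array number, 3 and 4 against 1 and 2. Array number therefore cannot be told apart from label within these slides. With slide as a block it enters E2 and Dex+E2 against vehicle, Dex+E2 against Dex and the average E2 effect.

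The design, the gene lists, the alternatives and the rule for named genes were chosen before the data were examined. Named are the 8 genes with the largest increase and the 8 with the largest decrease among called genes with symbols whose arrays did not overlap between the groups, up to 4 called members of each list with at least 2 of them, the 5 genes with the smallest unadjusted p where fewer than 5 were called, and a fixed panel of receptor and hormone target genes. The same rule was applied to slide 1. The levels of further list members and the per-array levels of Klf15, Map3k6, Cebpd, Mt1 and Mt2 are shown because of what was seen in the data. The planned normexp correction of mean signals was not run because the files used here hold no mean signal column, and it was run on median signals in its place. That alternative and the fits on only the arrays numbered 1 and 2, or 3 and 4, were chosen after seeing the data. The restriction to numbers 1 and 2 was made because glucocorticoid target genes went against the labels of arrays numbered 3 and 4. It selects arrays by the outcome, so its counts are given as an alternative, its p-values do not test the treatments, and no genes are named from it. For Dex against vehicle its arrays are those of slide 1, and genes are named from the planned fit within that slide.

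The procedure was tested on simulated data of 17529 genes, with 50 genes changed at each size. For Dex against vehicle on all 16 arrays it recovered 44% of genes changed 1.5-fold, 70% at 2-fold, 92% at 3-fold and 96% at 4-fold. For the interaction the shares were 30%, 72%, 86% and 88%, and for Dex against vehicle on slide 1 they were 22%, 76%, 84% and 92%. At 2-fold, 3-fold and 4-fold the median fitted fold for Dex against vehicle on all 16 arrays was 2.01, 3.01 and 4.03. Simulated changes thus followed the labels. Measured Per1 rose 6.58-fold on slide 1, went against some labels, and was not called over all 16 arrays (limma adjusted p = 0.572). The simulated noise was independent between genes and arrays and had the same spread in every label. Measured spread was unequal, with a median absolute log2 difference of 0.182 between Vehicle 1 and 2 and 0.080 between Dex 1 and 2. The shares therefore describe only genes that follow their labels under such noise, and may differ for these arrays. A fit that calls no gene does not exclude responses of these sizes. Pairs of arrays within a group were compared with the scatter of replicate spots. The share of replicated probes beyond 2 spot errors was lowest for Dex+E2 1 and 2 (32.9% of 140) and Dex 1 and 2 (38.5% of 148), so no pair looked like 1 scan deposited again. That scatter leaves out labelling and hybridisation, so the check cannot tell separate cultures from repeat hybridisations, and each array was counted as 1 sample because the labels give it as one. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.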

Results

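Transcript levels were measured in HL-1 cells, a mouse atrial cardiomyocyte line that keeps a contractile phenotype in culture, after 6 h with vehicle, the synthetic glucocorticoid dexamethasone (Dex, 100 nM), the estrogen 17β-estradiol (E2, 10 nM) or both. Each treatment had 4 arrays, and each array measured 41174 probes. The series asks how glucocorticoid and estrogen signals oppose each other in cardiomyocytes. Levels are log2 values relative to the 75th percentile of the array.

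The receptors and their best-known targets were examined first. Nr3c1, which encodes the glucocorticoid receptor, was well above background on 16 of 16 arrays, at 2.02 ± 0.20 (SD, n = 4) on the arrays labelled vehicle. Esr2, encoding estrogen receptor beta, was measured on 16 arrays at low levels between -2.66 and -1.77, as was the G protein-coupled estrogen receptor gene Gper1, at -2.08 ± 0.51 (SD, n = 4) on the arrays labelled vehicle. Esr1, encoding estrogen receptor alpha, was well above background on 0 of 16 arrays, the progesterone receptor gene Pgr on 1 and Lcn2 on 4, so these genes were not tested. Zbtb16 had no probe that could be named.

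Glucocorticoid target genes went against the labels of 4 arrays. Per1, a clock gene with glucocorticoid response elements, lay between 1.75 and 1.99 on Vehicle 4, Dex 1, 2 and 4, E2 4, and Dex+E2 1, 2 and 4. On the other 8 arrays it lay between -1.29 and -0.75. Within the group labelled vehicle the level was -0.27 ± 1.35 (SD, n = 4), and within the group labelled Dex it was 1.14 ± 1.54 (SD, n = 4). Klf15, a glucocorticoid-induced transcription factor of muscle and heart, was at 2.51 on Vehicle 4 and 0.58 on Dex 3, and Map3k6 was at 1.55 and -0.63 on these arrays. All comparisons that follow therefore speak of arrays by their label, and no direction drawn from them is known to be that of the hormone.

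**Figure D1:**
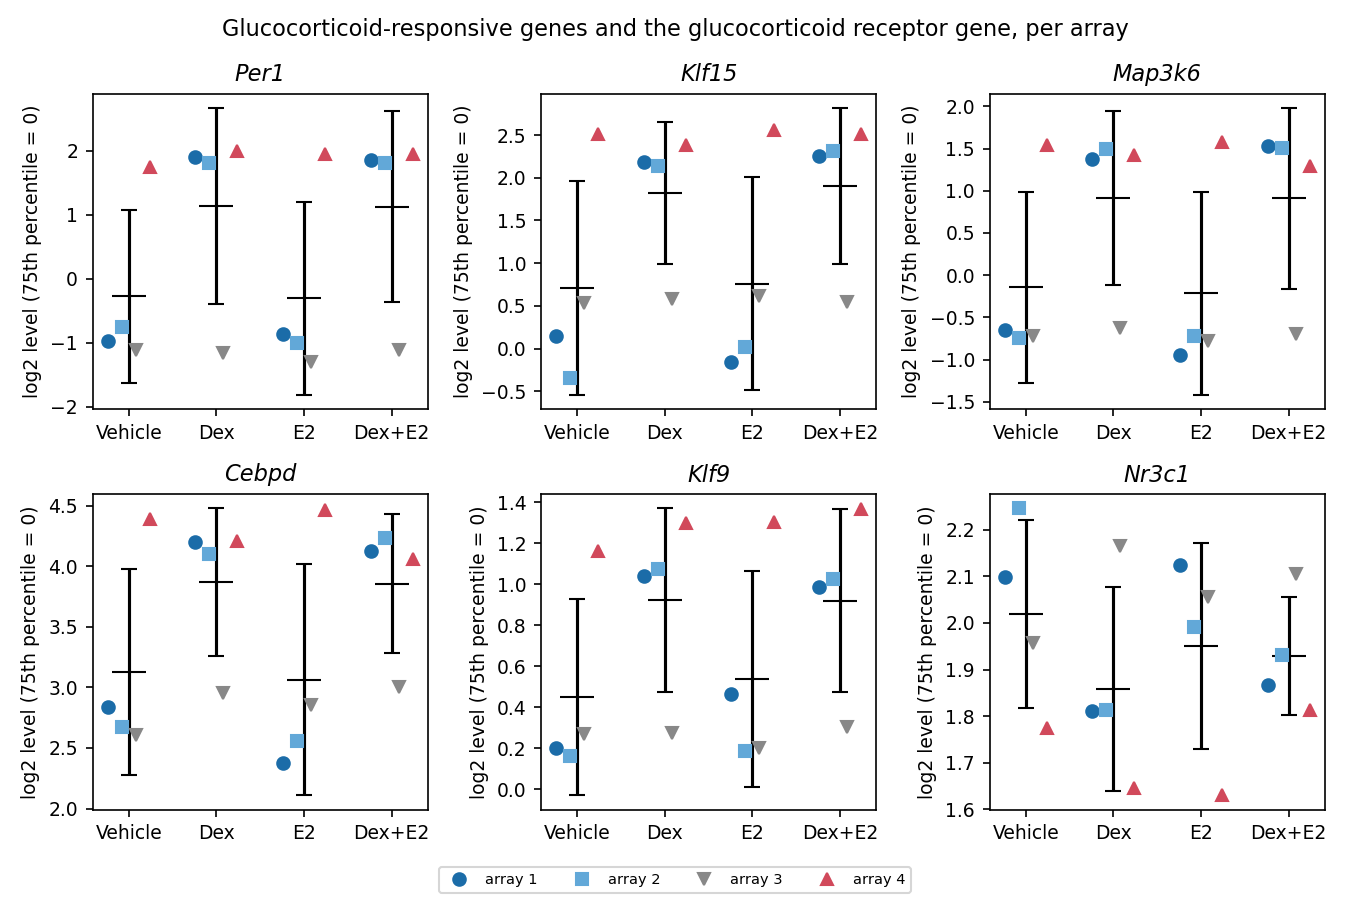
Log2 levels (75th percentile of each array = 0) of 5 glucocorticoid-responsive genes and the glucocorticoid receptor gene Nr3c1 on each of the 16 arrays, by label on the x axis, with symbols for the array number and black bars for mean ± SD (n = 4). Per1 is at 1.75 on Vehicle 4 and 1.95 on E2 4, and at -1.17 on Dex 3 and -1.11 on Dex+E2 3.

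The response to the glucocorticoid alone was asked by setting the arrays labelled Dex against those labelled vehicle. Per1 differed by 1.41 ± 0.93 (SE, n = 4 per group), Fkbp5, a chaperone of the glucocorticoid receptor, by 0.54 ± 0.29, Tsc22d3, which encodes the anti-inflammatory protein GILZ, by 0.42 ± 0.17, Klf9 by 0.47 ± 0.30 and Sgk1 by 0.04 ± 0.19. Nr3c1 differed by -0.16 ± 0.13, Gper1 by -0.59 ± 0.26, Esr2 by -0.31 ± 0.19, the estrogen target Greb1 by 0.69 ± 0.23 and Ptgds by 0.01 ± 0.09. None of these passed the test. The 5 smallest unadjusted p-values belonged to Rfx1 at -0.73 ± 0.16, Lexm at -2.17 ± 0.50 with 1 of 4 arrays labelled Dex above background, Kcnh6, a potassium channel gene, at -0.64 ± 0.15, XM_006508439 at -0.25 ± 0.06, and Dio1, which was at least 1.47-fold lower on the arrays labelled Dex. All 5 had a limma adjusted p of 0.448. Limma called 0 of 17773 genes, with 1944 at an unadjusted p under 0.05 where 889 are expected by chance. With slide as a block it called 0, with 1758 at an unadjusted p under 0.05.

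As groups, 22 of the 30 measured glucocorticoid-induced genes had positive differences on the arrays labelled Dex, with a median of 0.24 (camera adjusted p = 0.0108, and adjusted p = 0.953 with an estimated correlation). Genes of cholesterol synthesis were positive in 20 of 22 (median 0.14, adjusted p = 0.000698), genes of ER stress and the amino acid response in 18 of 22 (median 0.15, adjusted p = 0.00164), and antioxidant and metallothionein genes in 17 of 23 (median 0.04, adjusted p = 0.0183). Interferon-response genes were positive in 3 of 18 (median -0.20, adjusted p = 0.0147). With an estimated correlation the ER stress list had an adjusted p = 0.826, and the other 3 had an adjusted p = 0.953 with an estimated correlation. Called members numbered 0 over all genes in these 5 lists, and adjusted over the list alone 2 ER stress genes were higher and 0 members of the other 4 lists were called. With slide as a block the adjusted p was 0.0501 for the glucocorticoid list, 7.47e-06 for cholesterol synthesis, 0.0031 for ER stress, 0.0884 for antioxidant genes and 0.00261 for interferon-response genes. The cholesterol, ER stress and interferon calls of that fit had an adjusted p = 0.445, 0.441 and 0.556 with an estimated correlation.

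On slide 1, which held Vehicle 1 and 2 and Dex 1 and 2, 39 genes were called, 33 higher and 6 lower on the arrays labelled Dex. Trim67 rose by 4.46 ± 0.12 on the log2 scale (SE, n = 2 per group, limma adjusted p = 0.0127), Arrdc2 by 3.45 ± 0.23, Tent5b by 2.82 ± 0.12, Per1 by 2.72 ± 0.11, Lrg1 by 2.36 ± 0.15, the lipid droplet gene Plin4 by 2.32 ± 0.18, Klf15 by 2.26 ± 0.18 and Map3k6 by 2.14 ± 0.09. The transcription factor gene Cebpd rose by 1.40 ± 0.08 and the metallothionein gene Mt1 by 1.21 ± 0.08. The sarcomere genes Myoz2, a calcineurin-binding Z-disc protein, and Myom2, a protein of the M-band, rose by 1.36 ± 0.10 and 1.21 ± 0.10, and they were the 2 called of 24 measured sarcomere genes. Among genes that fell, Nmrk2, a nicotinamide riboside kinase gene of muscle, was at -1.64 ± 0.10, the ephrin gene Efnb3 at -1.51 ± 0.11, and Parm1 at -0.80 ± 0.06. Entpd2 was at -2.54 ± 0.20 with 1 of 2 arrays labelled Dex above background, and Adgb was at least 3.1-fold lower on the arrays labelled Dex.

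Of the 30 glucocorticoid-induced genes, 7 were higher and 0 lower on slide 1, and adjusted over the list alone 17 were higher and 1 lower (median 0.44, camera adjusted p = 2.41e-12, and adjusted p = 0.408 with an estimated correlation). Cebpb was the called member of this list besides Arrdc2, Per1, Klf15, Map3k6, Cebpd and Mt1, at 1.35 with an adjusted p of 0.039. Interferon-response genes were positive in 2 of 18 (median -0.31, adjusted p = 0.000614, and adjusted p = 0.523 with an estimated correlation), with 0 called over all genes and 5 lower adjusted over the list alone. Cytokine and NF-kB genes were positive in 1 of 14 (median -0.36, adjusted p = 0.00275, and adjusted p = 0.523 with an estimated correlation), with 0 called over all genes and 5 lower adjusted over the list alone. Cholesterol synthesis genes were positive in 19 of 22 (median 0.24, adjusted p = 0.000614, and adjusted p = 0.737 with an estimated correlation), and ER stress genes in 16 of 22 (median 0.18, adjusted p = 0.00275, and adjusted p = 0.523 with an estimated correlation). Fatty acid metabolism genes and antioxidant and metallothionein genes also passed upwards (camera adjusted p = 0.039 and 0.0275) and TGF-beta and BMP target genes downwards (0.039), with an adjusted p = 0.523, 0.585 and 0.523 with an estimated correlation. With 2 residual degrees of freedom on this slide a list can hardly pass with an estimated correlation, so those values do not decide. The count of 39 rests on 2 arrays per group. The median absolute log2 difference across genes was 0.182 between Vehicle 1 and 2 and 0.080 between Dex 1 and 2. Vehicle 1 correlated at 0.973 to 0.982 across genes with every other array. On the second principal component of the 16 arrays Vehicle 1 lay at 67.4, and the other arrays lay between -30.2 and 4.35. Leaving out 1 array takes the spread from the remaining pair of the other label alone, and the count was then 0 without Dex 1, 0 without Dex 2, 1572 without Vehicle 2 and 6748 without Vehicle 1. With both pairs it was 1 when the variance prior had no trend.

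The 39 genes were then followed on the arrays numbered 3 and 4, which were not on slide 1 and which share a slide within each label. From array 3 to array 4, genes went in the direction of their slide 1 difference in 37 of 39 for the label vehicle, 37 for Dex, 39 for E2 and 38 for Dex+E2. The exceptions were Adgb and Entpd2, which were lower on the arrays labelled Dex of slide 1. Adgb rose by 2.63 for vehicle, 1.47 for Dex and 0.67 for Dex+E2, and Entpd2 by 0.12 for vehicle and 0.75 for Dex. The median ratio of the difference between arrays 4 and 3 to the slide 1 difference was 1.03, 0.90, 1.06 and 0.91. Between arrays 2 and 1 of the same labels the ratio was -0.03, -0.01, 0.06 and 0.02. For vehicle and Dex the call on slide 1 itself favoured small values, so only those for E2 and Dex+E2 are independent of it. Between labels, Dex 3 minus Vehicle 3 gave a median ratio of 0.05, Dex 4 minus Vehicle 4 of -0.05, Dex+E2 3 minus E2 3 of 0.02 and Dex+E2 4 minus E2 4 of -0.09.

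**Figure D2:**
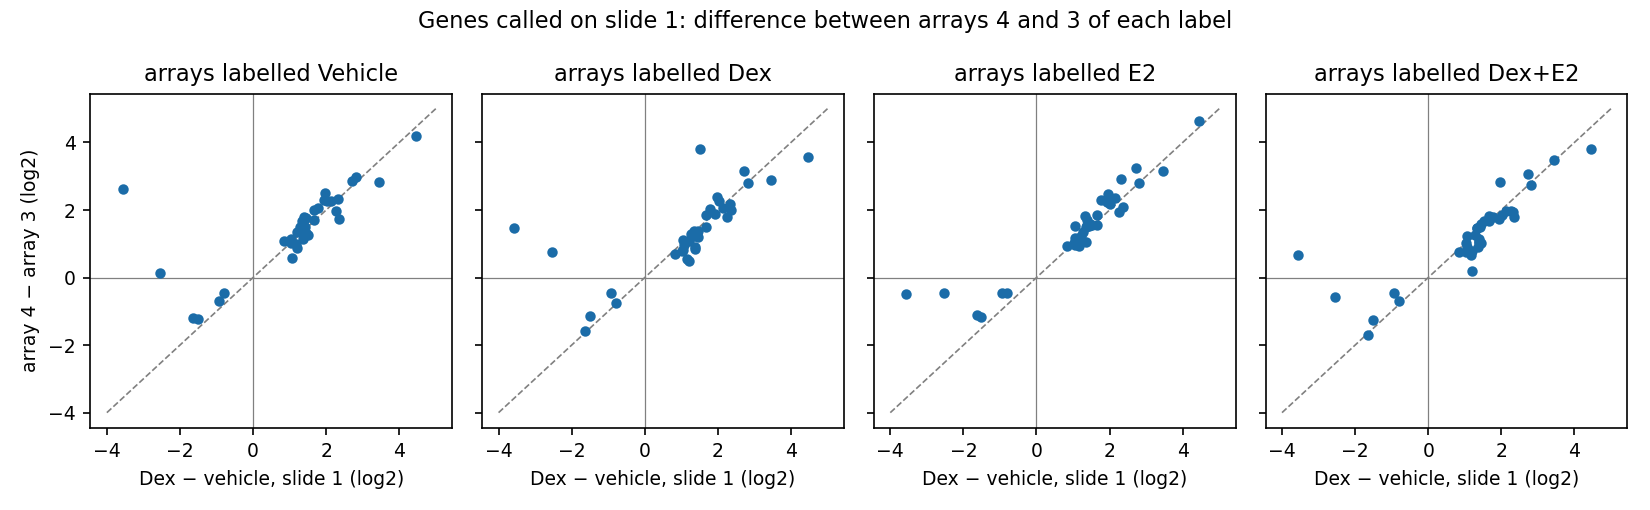
Log2 difference between arrays 4 and 3 of each label (y axis) against the log2 difference between Dex and vehicle arrays on slide 1 (x axis), 1 point for each of the 39 genes called there, with a dashed line of equal values. The median ratio of the y to the x values is 1.03, 0.90, 1.06 and 0.91 from left to right.

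The response to estradiol alone was asked by setting the arrays labelled E2 against those labelled vehicle. Tff1, a classical estrogen target, was at -4.86 ± 0.24 (SD, n = 4) against -5.89 ± 0.08, a difference of 1.03 ± 0.20 (SE), with 4 of 4 arrays labelled E2 and 3 of 4 labelled vehicle above background. Greb1 differed by 0.42 ± 0.23 and the Wnt antagonist gene Sfrp5 by 0.61 ± 0.12, while Utf1, Olfr1419 and AK087301 differed by 0.66, 0.74 and 0.69. None of these passed the test, and limma's adjusted p was 0.975 for each. Greb1 was at -2.295 and -2.288 on Vehicle 1 and 2, and at -1.259 and -1.292 on Vehicle 3 and 4. On the arrays labelled E2 it lay between -1.646 and -1.174, so its difference rests on Vehicle 1 and 2. On slide 2, which held Vehicle 3 and 4, E2 1 and 2 were at -1.174 and -1.458. Among estrogen-induced genes 13 of 24 had positive differences (median 0.01, camera adjusted p = 0.384), with 0 called over all genes and 1 higher adjusted over the list alone. Cholesterol synthesis genes were positive in 21 of 22 (median 0.10, adjusted p = 0.00164, and adjusted p = 0.953 with an estimated correlation). Interferon-response genes were positive in 1 of 18 (median -0.13, adjusted p = 0.0162, and adjusted p = 0.953 with an estimated correlation). In both of these lists 0 members were called, over all genes and adjusted over the list alone.

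Limma called 0 genes between the labels E2 and vehicle, with 686 at an unadjusted p under 0.05, 0 with slide as a block (1458) and 0 within slide 2 (1462). The cholesterol and interferon lists had adjusted p-values of 0.0948 and 0.832 with slide as a block, and 0.421 and 0.397 within slide 2. Instead, 8 other lists passed on slide 2, all upwards, and each had an adjusted p = 0.454 with an estimated correlation. Hypoxia and glycolysis genes were positive in 19 of 20 on slide 2 (median 0.28, adjusted p = 6.06e-10, and adjusted p = 0.454 with an estimated correlation) and in 17 of 20 with slide as a block (median 0.24, adjusted p = 5.85e-06, and adjusted p = 0.392 with an estimated correlation). Sarcomere genes were positive in 19 of 24 on slide 2 (median 0.16, adjusted p = 0.000666, and adjusted p = 0.454 with an estimated correlation). Slide 2 sets Vehicle 3 and 4, which differed as described above, against E2 1 and 2.

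The combined treatment was compared with vehicle. Greb1 differed by 0.90 ± 0.23 (SE, n = 4 per group), Per1 by 1.40 ± 0.93, Fkbp5 by 0.40 ± 0.29 and Tsc22d3 by 0.39 ± 0.17 on the arrays labelled Dex+E2. The smallest unadjusted p belonged to Glrx, a glutaredoxin gene, at -0.32 ± 0.06. Oxct2a was at -2.39 ± 0.52 with 1 of 4 arrays labelled Dex+E2 above background, and AK034802, X14489 and Cfap157 were at least 3.64-fold, 1.91-fold and 1.23-fold lower. None of these passed the test, with limma adjusted p-values of 0.711 to 0.721. Limma called 0 genes, with 999 at an unadjusted p under 0.05, and 0 with slide as a block (982). No slide held both labels.

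Glucocorticoid-induced genes were positive in 20 of 30 between Dex+E2 and vehicle (median 0.20, camera adjusted p = 0.0248), cholesterol synthesis genes in 17 of 22 (median 0.10, adjusted p = 0.0147) and ER stress genes in 19 of 22 (median 0.14, adjusted p = 0.0127). Interferon-response genes were positive in 2 of 18 (median -0.22, adjusted p = 0.00164) and cytokine and NF-kB genes in 1 of 14 (median -0.22, adjusted p = 0.0433). Each of these 5 lists had an adjusted p = 0.953 with an estimated correlation, and 0 called members over all genes and adjusted over the list alone. With slide as a block the adjusted p was 0.0696, 0.021, 0.35, 0.111 and 0.154 in the same order, and the cholesterol call of that fit had an adjusted p = 0.778 with an estimated correlation. That fit passed 10 lists, all upwards, among them hypoxia and glycolysis genes (18 of 20 positive, median 0.30, adjusted p = 2.27e-10, and adjusted p = 0.324 with an estimated correlation), extracellular matrix genes (15 of 23 positive, median 0.23, adjusted p = 2.2e-05, and adjusted p = 0.324 with an estimated correlation) and sarcomere genes (19 of 24 positive, adjusted p = 5.6e-05, and adjusted p = 0.34 with an estimated correlation). Estrogen-induced genes were also among them (14 of 24 positive, adjusted p = 0.00954, and adjusted p = 0.324 with an estimated correlation). With slide as a block, lists that passed numbered 6 between E2 and vehicle, 5 between Dex+E2 and Dex, 3 between Dex+E2 and E2 and 2 for the interaction, and 0 passed in any comparison with an estimated correlation. Position and label cannot be told apart in these fits, the interaction excepted, and position enters Dex+E2 against vehicle more than once. Array number also enters those of E2 and Dex+E2 against vehicle and of Dex+E2 against Dex.

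What estradiol adds to the glucocorticoid was asked by setting the arrays labelled Dex+E2 against those labelled Dex. For the glucocorticoid targets the differences were -0.01 ± 0.93 (SE, n = 4 per group) for Per1, -0.14 ± 0.29 for Fkbp5 and -0.02 ± 0.17 for Tsc22d3. The estrogen target Greb1 was at 0.21 ± 0.23. The smallest unadjusted p-values belonged to BC116864 at 0.64 ± 0.12, ENSMUST00000184874 at 0.64 ± 0.13, the keratin gene Krt84 at 0.93 ± 0.19, the cytokine gene Il16 at 0.71 ± 0.15 and Pnmal1 at 0.47 ± 0.10, with limma adjusted p-values of 0.951 to 1. Limma called 0 genes, with 574 at an unadjusted p under 0.05, 0 with slide as a block (2131) and 0 within slide 3 (2275). No list passed over all 16 arrays. Within slide 3 hypoxia and glycolysis genes were positive in 17 of 20 (median 0.30, camera adjusted p = 0.00837, and adjusted p = 0.922 with an estimated correlation), and with slide as a block in 18 of 20 (median 0.34, adjusted p = 7.47e-06, and adjusted p = 0.394 with an estimated correlation).

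What the glucocorticoid adds to estradiol was asked by setting the arrays labelled Dex+E2 against those labelled E2. Per1 differed by 1.43 ± 0.93 (SE, n = 4 per group), Fkbp5 by 0.26 ± 0.29, Tsc22d3 by 0.30 ± 0.17, Sgk1 by 0.25 ± 0.19 and Greb1 by 0.48 ± 0.23. The smallest unadjusted p-values belonged to Mettl24 at -0.63 ± 0.14, Sfrp5 at -0.53 ± 0.12, Padi1 at -0.40 ± 0.10, Trim14 at -0.95 ± 0.24 with 1 of 4 arrays labelled Dex+E2 above background, and Sprr2e at -0.30 ± 0.08, all with a limma adjusted p of 1. Limma called 0 genes, with 732 at an unadjusted p under 0.05, 0 with slide as a block (462) and 0 within slide 4 (650). Glucocorticoid-induced genes were positive in 24 of 30 (median 0.25, camera adjusted p = 0.000816, and adjusted p = 0.953 with an estimated correlation), with 0 called over all genes and adjusted over the list alone. That list had an adjusted p of 0.00215 with slide as a block (adjusted p = 0.778 with an estimated correlation) and 0.431 within slide 4, where E2 4 and Dex+E2 3 lay and where hypoxia and glycolysis genes were positive in 17 of 20 (median 0.15, adjusted p = 2.56e-08, and adjusted p = 0.666 with an estimated correlation).

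Whether estradiol alters the glucocorticoid response was asked by the Dex by E2 interaction. It was 0.02 ± 1.32 (SE) for Per1, -0.28 ± 0.41 for Fkbp5, -0.12 ± 0.24 for Tsc22d3 and -0.09 ± 0.43 for Klf9. The smallest unadjusted p-values belonged to Luzp1 at 0.62 ± 0.14, the histone demethylase gene Kdm5a at 0.58 ± 0.14, Zc3h13 at 0.58 ± 0.15, Arfgap2 at -0.33 ± 0.09 and Dicer1, which encodes the nuclease of microRNA processing, at 0.49 ± 0.13, each with a limma adjusted p of 0.999. Limma called 0 genes, with 663 at an unadjusted p under 0.05, and 0 with slide as a block (898). No slide held all 4 labels. Cholesterol synthesis genes were positive in 3 of 22 (median -0.18, camera adjusted p = 0.000816, and adjusted p = 0.953 with an estimated correlation), and had an adjusted p of 0.000229 with slide as a block (adjusted p = 0.551 with an estimated correlation). In this list 0 members were called, over all genes and adjusted over the list alone.

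The planned comparison of the glucocorticoid response without and with estradiol needed genes called for the average Dex effect, and limma called 0 of them, with 1788 at an unadjusted p under 0.05. For the average E2 effect it called 0 (653), 6 with slide as a block (4 higher, 2 lower) and 0 with slide and replicate number together as blocks. Position and label cannot be told apart in the fits with slide as a block, and for the average E2 effect array number enters as well. Across the 17773 genes the average Dex and E2 effects correlated at Pearson r = 0.232 and Spearman rho = 0.229, with a jackknife error over arrays of 0.348, and at r = -0.104 with slide as a block. Genes are not independent replicates, and that error, taken without the block, exceeds the unblocked correlation.

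The counts were repeated without the arrays numbered 3 and 4, because those were in doubt. Limma then called 420 genes between the labels Dex and vehicle (211 higher, 209 lower), 663 between Dex+E2 and vehicle (311 higher, 352 lower) and 594 between Dex+E2 and E2 (395 higher, 199 lower). It called 0 between E2 and vehicle (3603 at an unadjusted p under 0.05), 0 between Dex+E2 and Dex (693) and 0 for the interaction (2109). With 2 arrays per label, these counts of 0 do not show that estradiol changed no genes. The other 3 counts ranged over normalization, filter, probe and prior choices from 173 to 507, 223 to 820 and 165 to 747. They were 39, 6 and 223 with only the arrays of the compared labels, the first of these being the slide 1 fit, and 167, 317 and 250 with the replicate number as a block. The excess of higher genes between Dex+E2 and E2 was absent with quantile normalization (333 higher, 336 lower) and small with the deposited log2 table (313 higher, 302 lower). Median scaling kept it, with 130 higher and 35 lower, and gave 141 higher and 32 lower between Dex and vehicle. Leaving out an array leaves 1 label with a lone array and takes the spread from the other labels. The 3 counts then went from 27 to 2269, 105 to 3345 and 121 to 287, and the counts of 0 reached 1492 between E2 and vehicle without Vehicle 1, 31 between Dex+E2 and Dex without Dex+E2 1 and 138 for the interaction without Vehicle 2. On only the arrays numbered 3 and 4 it called 0 in all 6 comparisons, with 780, 203, 984, 710, 539 and 213 at an unadjusted p under 0.05. The arrays left out were chosen because target genes of the hormone went against their labels, so the higher counts are not independent evidence of a treatment effect.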

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

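The 4 tests of the pattern of arrays 3 and 4 and the tests against other splits were chosen only after the result was seen. Levels of 16 genes and 6 measures of array quality were checked per label for an array far from the other 3 of its group. Of 88 such checks 23 found one, where about 1 in 20, or 4.4, are expected by chance: 21 of 64 checks of genes and 2 of 24 checks of array quality. Of the genes, 10 belonged to the panel fixed before the data were examined and had 10 such arrays in 40 checks (2 expected by chance), while Klf15, Cebpd, Map3k6, Mt1, Mt2 and Tff1 were added after their values were seen and had 11 in 24 checks.

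On Vehicle 4, Per1 stood at 1.75 (other 3 arrays -1.11 to -0.75), Klf9 at 1.16 (0.16 to 0.27), Cebpd at 4.40 (2.60 to 2.84), Map3k6 at 1.55 (-0.75 to -0.65) and Esr2 at -2.50 (-1.88 to -1.77). On E2 4, Per1 stood at 1.95 (-1.29 to -0.86), Map3k6 at 1.58 (-0.94 to -0.72), Mt1 at 5.47 (4.12 to 4.25), Sgk1 at 1.09 (0.58 to 0.65) and Fkbp5 at -0.15 (-0.97 to -0.85). On Dex 3, Per1 stood at -1.17 (1.81 to 1.99), Map3k6 at -0.63, Klf15 at 0.58, Cebpd at 2.95 (4.11 to 4.21) and Tsc22d3 at 1.20 (1.43 to 1.47). On Dex+E2 3, Per1 stood at -1.11 (1.82 to 1.95), Map3k6 at -0.69 (1.29 to 1.54), Klf15 at 0.54, Cebpd at 3.01 (4.06 to 4.24) and Mt2 at 4.63 (6.09 to 6.18). Apart from these, Ptgds stood at 1.85 on E2 1 (2.03 to 2.07). Spots left out for an outlier flag numbered 296 on Dex 3 (88 to 120 on the other Dex arrays), and the mean of negative controls was 11.5 on E2 4 (12.4 to 12.5 on the other E2 arrays).

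The pattern in these values is that glucocorticoid-responsive genes differed between arrays 3 and 4 of every label, including labels without Dex. A difference between slides is argued against, because arrays 3 and 4 of each label shared a slide and the lower quartile of the ratio of their difference to the slide 1 difference was still 0.757 or more in each label. Array brightness or background is argued against as well, because 97.6% or more of the genes called on the arrays numbered 1 and 2 (417 to 420 measured in each label) went in the slide 1 direction, among them genes that were higher and genes that were lower. Mislabelled arrays are a candidate explanation, since the median ratio was 0.902 or more in every label and 2 high arrays without Dex in the label (Vehicle 4 and E2 4) had 2 low arrays with Dex in the label (Dex 3 and Dex+E2 3). Cultures whose treatment differed from the label cannot be told apart from that, because Dex minus no Dex within number 3 or 4 had median ratios no farther from 0 than -0.088 under either, so no array was relabelled and which arrays were exchanged, if any, stays open.

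The counts of called genes were also set against other splits of the same arrays. For Dex against vehicle, E2 against vehicle, Dex+E2 against vehicle, Dex+E2 against Dex and Dex+E2 against E2, 35 of 35 splits gave at least the real count of 0, which any split must, so these shares carry no information. The highest other splits called 789, 502, 799, 8 and 1 genes. The split with 789 set Vehicle 1 and 2 and Dex 1 and 2, which are slide 1, against the rest, and that with 502 set Vehicle 1 and 2 and E2 1 and 2 against arrays 3 and 4. The split with 799 set Vehicle 1, 2 and 3 and Dex+E2 1 against the rest, which follows neither slide nor array number. Each of these counts is the highest of the other splits, and no reference for such a maximum was drawn. A structure of the samples other than the labels is therefore possible, and no test of it was run. Principal component 1 of all arrays held 27.1% of the variance. On it Vehicle 1, 2 and 3, E2 1 and Dex+E2 1 lay between -52.61 and -17.96. All other arrays lay between 5.93 and 24.32. The split with 799 thus set the negative arrays of its labels against the rest, while the splits with 789 and 502 did not follow this component. For the interaction, the average Dex effect and the average E2 effect, 100 of 100 regroupings gave at least the real 0, and the highest others called 336, 126 and 229.

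For the shifts of gene lists chance could not be excluded in any comparison that had one. For Dex against vehicle 16 of 35 splits gave as many as the real 5 (highest other 8), for E2 against vehicle 31 of 35 as many as 2 (highest 9), for Dex+E2 against vehicle 8 of 35 as many as 5 (highest 7), for Dex+E2 against E2 33 of 35 as many as 1 (highest 6), and for the interaction 90 of 100 as many as 1 (highest 10).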

How the results depend on the processing

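The normexp alternative and the fits on only the arrays numbered 1 and 2, or 3 and 4, were chosen after seeing the data, and every other alternative before. With all 16 arrays, the 6 counts of 0 stayed 0 in every fit with an array left out and in every other alternative, with these exceptions: E2 against vehicle gave 1 gene without a trend, Dex against vehicle 39 within slide 1 and 420 with only arrays numbered 1 and 2, Dex+E2 against vehicle 663 and Dex+E2 against E2 594 with those arrays. Genes called for the average Dex effect numbered 1205 with those arrays and 0 to 1 with an array left out. Genes called for the average E2 effect numbered 5 without a trend, 6 with slide as a block, 0 with slide and replicate block together and 1 with only arrays numbered 1 and 2. The counts on arrays numbered 1 and 2 rest on a choice made from the outcome. With an array left out, fits in which 1 label has a lone array and the other labels give the spread, they went from 27 to 2269 for Dex against vehicle, 105 to 3345 for Dex+E2 against vehicle, 121 to 287 for Dex+E2 against E2, 0 to 1492 for E2 against vehicle, 0 to 31 for Dex+E2 against Dex and 0 to 138 for the interaction. Normalization, filter, probe and prior choices gave 173 to 507, 223 to 820, 165 to 747, 0 to 2, 0 to 0 and 0 to 1 in the same order. Among these choices the lowest value of each of the 3 nonzero counts came from median scaling. It gave 141 higher and 32 lower for Dex against vehicle and 130 higher and 35 lower for Dex+E2 against E2. For Dex+E2 against E2 quantile normalization gave 333 higher and 336 lower, and the deposited log2 table gave 313 and 302. With only the arrays of the compared labels the 3 counts were 39 (the slide 1 fit), 6 and 223, and with the replicate block 167, 317 and 250.

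The 39 genes of slide 1 became 64 (51 higher, 13 lower) with quantile normalization, 66 (58 higher, 8 lower) with median scaling, 9 without a filter, 97 with probes well above background on all 16 arrays, 16 with the mean of a gene's probes, 22 with every probe on its own, 1 without a trend, 21 with flagged spots kept, and 0 to 6748 with an array left out, fits in which 1 label has a lone array that is assumed to vary like the pair of the other. The correlation of average effects ranged from 0.092 to 0.487 with an array left out, and was -0.104 with slide as a block and -0.451 with slide and replicate block together. The 14 list shifts became 9 with quantile normalization, 9 with the deposited log2 table, 9 without a filter, 29 with slide as a block, 34 with slide and replicate block together, 38 with only arrays numbered 1 and 2, 0 with an estimated correlation and 6 to 22 with an array left out. The cause was not tested, except that fewer arrays, genes or probes enter some of these fits by construction. For named genes, 1070 of 1070 values over all 16 arrays stayed uncalled, 47 with another sign, and 145 of 236 values of slide 1 stayed called.

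The array numbers were not taken to pair the samples, because deviations of same-numbered arrays correlated at -0.156 to 0.463 and over 0.1 in only 13 of 24 pairs. For number 4 all 6 pairs were over 0.1 (lowest 0.107), and 9 of 16 arrays correlated best with their own number. No reference for that count was drawn. Per1 followed the labels on arrays numbered 1 and 2. For the 39 genes called on slide 1, numbers 3 and 4 differed little between labels with and without Dex. The median ratio to the slide 1 difference was 0.046 for Dex minus vehicle and 0.019 for Dex+E2 minus E2 within number 3. Within number 4 these were -0.054 and -0.088. A structure shared by array number therefore stays possible, and the pair correlations do not exclude it. With the replicate block the 6 counts were 0, list shifts 19, the correlation of average effects 0.232, and genes on slide 1 20. Signal over background limits the dim receptor genes, with Esr1 well above background on 0 arrays.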

Other observations

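The tests in this part were planned, and the list was picked for description after the values were seen. Hypoxia and glycolysis genes, among them the glucose transporter gene Slc2a1 and the lactate dehydrogenase gene Ldha, did not pass between any labels over all 16 arrays without a slide term. With slide as a block they passed in 4 of the 6 comparisons, all but Dex against vehicle (adjusted p = 0.326) and the interaction (0.613), and 0 of these held with an estimated correlation. They passed camera upwards within slides 2, 3 and 4, at adjusted p = 6.06e-10 for E2 against vehicle, 0.00837 for Dex+E2 against Dex and 2.56e-08 for Dex+E2 against E2. With an estimated correlation these were adjusted p = 0.454, 0.922 and 0.666. Each slide leaves 2 residual degrees of freedom, with which a list can hardly pass that version, so these values do not decide. On every one of these slides the label with the higher levels took positions 3 and 4 and the other label positions 1 and 2, so position and label cannot be told apart there. The same holds for the fits with slide as a block, apart from the interaction. On slides 2 and 3 array number cannot be told apart from label either. Slide 1 had the same layout, with Dex at positions 3 and 4, and there the list was positive in 7 of 20 (median -0.09, adjusted p = 0.939).

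Markers of other cell types were compared between labels, a comparison that cannot see such cells where all cultures hold them equally. Over all 16 arrays, between Dex and vehicle, 5 fibroblast markers had a median difference of -0.02 (camera adjusted p = 0.738), 8 smooth muscle markers 0.12 (0.243), 3 endothelial markers -0.18 (0.855) and 5 macrophage and leukocyte markers -0.06 (0.719).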
